A study of Homo sapiens with 6 samples.

How the data were processed

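RNA from CAL51 cells was profiled by bulk RNA sequencing in 6 libraries. CAL51 is an established human triple-negative breast cancer cell line. The titles place 2 libraries in each of 3 groups: control, TREX1 KO-1 and TREX1 KO-2. Per the series' design text, each knockout group carried a different guide RNA against TREX1, delivered with a CRISPR v2 lentivirus. The labels do not describe the control further, so whether it carried a guide or a cutting Cas9 is not given in the sources used here. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. The mouse bulk and single-cell parts of the series were not analysed here.

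Per the submitters' processing notes, the tools named for the series were fastp, STAR (version 2.7), featureCounts from Subread (version 2.0) and edgeR, with hg38 as the human genome build. The notes also name mm10, Cell Ranger and Seurat, which belong to data not used here. The gene annotation, the strand setting of the counting and any filter on genes are not given in the sources used here. Expression values were deposited by the authors as log2 CPM, the log2 of library-scaled counts, for 14788 genes in the 6 libraries. A second deposited table holds the authors' own comparisons of KO-1 with control, KO-2 with control and KO-2 with KO-1, each with a log2 fold change, a p-value and a false discovery rate. Its false discovery rates equal the Benjamini-Hochberg adjustment of its p-values. No row of either table carries the symbol TREX1, so the level of the targeted gene was not analysed here and the labels were not checked against it. ATRIP is given in its place, because its annotated exons overlap those of TREX1 on the same strand.

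The log2 CPM values share a minimum of -3.29 across libraries. Subtracting the prior of 0.102 CPM that this minimum stands for gave whole reads for 100% of the values, at a tolerance of 0.01 reads. Summed over genes, the recovered reads came to 22941234 and 25785055 for the control libraries, 16802681 and 18440036 for KO-1, and 13222933 and 20154836 for KO-2. At these depths 1 read was worth between 0.0383 and 0.0767 CPM. A gene with 0 reads in a library could therefore lie at up to 3 reads, or 0.115 to 0.230 CPM, from counting error alone. The 10 most abundant genes took between 2.71% and 3.04% of the reads of a library. Within each group the replicate libraries differed by more than sampling noise, with a chi-square per degree of freedom of 3.68 for control, 3.01 for KO-1 and 8.54 for KO-2. No libraries were therefore merged as repeats of 1 sequenced library, which does not show that they are independent samples.

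Genes with a log2 CPM of at least 0 (1 CPM) in at least 2 of the 6 libraries were tested, which kept 13765 genes and removed 1023. The values were used as deposited, without another pseudocount or scaling. A fold change is therefore on the scale of log2 of CPM plus the prior, which understates the change of genes with few reads. A group-means model over all 6 libraries was fitted with limma (version 3.58.1, in R 4.3.3), with moderated variances that follow a mean-variance trend, 3 residual degrees of freedom and 8.02 prior degrees of freedom. The contrasts were the mean of both guides against control, each guide against control, and KO-2 against KO-1. The last is the test of the difference between the guides. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested, with no minimum fold. All adjusted p-values for genes and gene lists below come from limma unless the authors' deposited table is named. Errors after a ± are the SD of 2 libraries or, for a fold change, the standard error (SE) from limma.

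The groups, tests, gene lists, alternative settings and the rule for naming genes were fixed before the data were examined. The rule took, for both guides against control, the 12 highest and 12 lowest log2 fold changes among called genes whose 4 knockout libraries all lay on one side of both control libraries, with a mean log2 CPM of at least 1. Clone-based names were left out, and 1 of the 12 highest is not reported here. For KO-2 against KO-1 it took 5 in each direction in the same way, and for each list up to 4 members with the smallest p. A further member of a list named below was chosen after its values were seen. The 25 lists covered interferon-stimulated genes, interferon ligands and T cell chemokines, NF-kB target genes, nucleic acid sensing, nucleic acid metabolism genes mutated in interferonopathies together with other DNases, MHC class I, MHC class II, immune checkpoint ligands, p53 target genes, ATR signalling, nucleotide excision repair, homologous recombination, DNA replication and G1/S, G2/M, epithelial markers, mesenchymal markers, hypoxia and glycolysis, cholesterol synthesis, the unfolded protein response, immediate early genes, mitochondrially encoded genes, histone genes, cytosolic ribosomal proteins, markers of leukocytes, endothelium and red cells, and the neighbours of TREX1. Lists with at least 5 genes tested, 22 in all, were tested against all other genes with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over lists within a comparison. Camera with an estimated correlation and fry, all from limma, were run beside it. The estimated correlation rests on 3 residual degrees of freedom.

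Both guides were compared with the same control libraries. Chance values for what they share came from 20 simulations with no gene changed, in which all 6 libraries, the controls included, were simulated noise. The planned comparison with the authors' deposited table assumed a contrast of both guides, which that table does not give, so it was made for each of its 3 comparisons. Gene positions are from the GENCODE 29 annotation of GRCh38, the assembly also called hg38, in which 93.9% of the gene symbols in the table were found. Exon overlaps come from the same annotation. Because the strand setting is not given, values of genes whose exons overlap a gene on the opposite strand are uncertain, as are those of genes with near-identical copies, such as histones, ribosomal proteins and the CXCL1, CXCL2 and CXCL3 group.

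The fit was tested on simulated data made from the means and depths of these libraries, with 13765 genes. For both guides against control, 68.6% of genes changed by log2 0.5 and 86.8% of those changed by log2 1 were called, and 6.83% of calls were false. With no change in any gene, 9 calls were made over 5 simulations. With the members of the interferon list raised, 41.5% passed at a change of log2 0.25, 67.7% at 0.5 and 95.9% at 1. The cutoff for a member was the largest unadjusted p called in the real data. Camera gave the list an unadjusted p below 0.05 in 5 of 5 simulations at each size. Of 500 random lists in data with no change, 2.80% had an unadjusted camera p below 0.05. Simulated genes varied independently and those outside the list did not change, so these list results do not test the preset correlation.

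The alternatives were other pseudocounts, no filter and a stricter filter, equal library medians, quantile normalization, no mean-variance trend, robust variances, a replicate block, the knockout libraries as 1 group, 2 stricter thresholds, other tests of lists, and each library left out. Voom on the recovered reads, thinning to the smallest total, and removal of trends with GC content and transcript length were added after the data were seen. A scan of 7-base words in 3' UTRs was also added then. It used 12225 genes with an annotated 3' UTR in GENCODE 29, 88.8% of those tested, and scored the 16225 words that at least 50 genes hold by the shift of their log2 fold changes, after removing trends with GC content, UTR length and expression. The longest annotated 3' UTR of each gene was searched. Its null came from 100 permutations of genes. In simulated data, 20 of 20 words given a log2 shift of 0.2 in 150 to 300 genes ranked first. The scan and the figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.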

Results

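Transcripts were measured in CAL51 cells, a human triple-negative breast cancer line, in 2 control libraries, 2 libraries of TREX1 knockout guide 1 (KO-1) and 2 of guide 2 (KO-2). TREX1 is the major cytosolic DNA exonuclease, and its loss is known to let DNA accumulate and engage the cGAS-STING pathway. Depth ranged from 13222933 reads in KO-2 replicate 1 to 25785055 in control replicate 2, and 13765 genes were tested. The first principal component of log2 CPM held 46.8% of the variance and separated the control libraries, at -27.9 and -26.4, from KO-1 at 22.4 and 21.5 and KO-2 at 2.35 and 8.12. The second held 25.1% and set KO-2 replicate 1, at -33.4, apart from the other 5 libraries, which lay between 5.18 and 8.94. KO-2 replicate 1 was also the shallowest library and had 61 genes at 0 reads, against 5 to 16 in the others. The SD of the log2 difference between replicates was 0.39 for KO-2, 0.28 for KO-1 and 0.24 for control. KO-2 replicate 2 correlated at a Pearson r of 0.9917 and 0.9918 with the KO-1 libraries, but 0.9880 with KO-2 replicate 1. Its r with the control libraries was 0.9868 and 0.9876. The third component, with 11.2% of the variance, set KO-2 replicate 2 at 21.6, and the other libraries at -7.87 to -0.74. By correlation KO-2 replicate 2 thus lay nearer KO-1 than its own replicate, which limits results for KO-2 and between the guides.

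**Figure D1:**
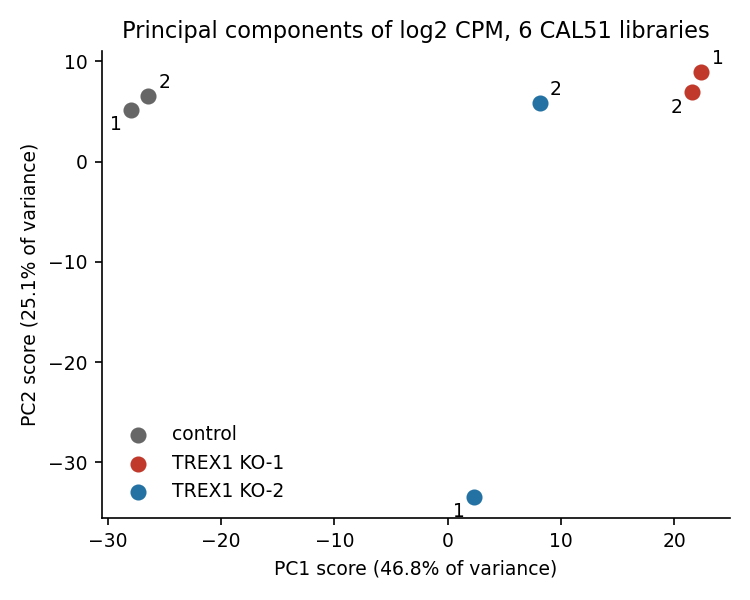
Scores of the 6 CAL51 libraries on the first principal component (horizontal, 46.8% of the variance) and the second (vertical, 25.1%) of log2 CPM, with the replicate number beside each point and the group in colour. The control libraries lie left of all knockout libraries, and KO-2 replicate 1 lies below the rest at -33.4.

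TREX1 itself was not analysed here. ATRIP, which encodes the partner protein of the ATR kinase, lies on chromosome 3 from 48446710 to 48467645 (hg38, plus strand), and its exons overlap those of TREX1 on the same strand. Its log2 CPM was 4.76 ± 0.05 in control, 4.34 ± 0.11 in KO-1 and 4.49 ± 0.06 in KO-2 (SD, n = 2 each). It fell with both guides together by a log2 fold change of -0.34 ± 0.09 (SE, adjusted p = 0.020) and with KO-1 by -0.41 (adjusted p = 0.015), and its value in KO-2 was -0.27 (adjusted p = 0.12). The call for both guides was lost without control replicate 1 (adjusted p = 0.13), without control replicate 2 (0.20) and without KO-1 replicate 2 (0.072). Because reads could come from either gene, ATRIP does not measure the knockout. Of 12 genes tested next to TREX1 on chromosome 3p21, 3 fell and 0 rose, with a median of -0.04 (camera adjusted p = 0.54).

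The comparison of the mean of both guides with control asked what differs on average in cells that carry a TREX1 knockout. Values given for both guides refer to this mean, so a gene changed with 1 guide alone can be called. Target genes of p53, the damage-responsive transcription factor, rose nearly as a block: 31 of 34 rose and 1 fell, with a median log2 fold change of 0.72. NF-kB target genes rose in 17 of 23 cases with 0 falling, at a median of 0.63. Genes of DNA replication and the G1/S transition moved the other way, with 33 of 45 falling, 0 rising and a median of -0.32. Interferon-stimulated genes, the known readout of cytosolic DNA sensing, were mixed: 9 of 39 rose, 2 fell and the median was 0.12.

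In all, 4068 of 13765 genes were called for the mean of both guides (29.6%), 2011 higher and 2057 lower. Most changes were small. The median absolute log2 fold change of called genes was 0.36, and 188 were changed at least 2-fold, of which 132 were higher and 56 lower. With library medians set equal the split moved to 2575 higher and 1598 lower, or 61.7% higher in place of 49.4%, while the median fold change of all genes moved from -0.01 to 0.04. The count fell to 1277 without control replicate 1 and 1508 without control replicate 2, to 2560 and 2557 without KO-1 replicates 1 and 2, and to 2201 with no mean-variance trend. Of 296 members of the lists that were called, 163 lost their call without control replicate 1, 157 without control replicate 2, 82 and 87 without KO-1 replicates 1 and 2, and 0 without either KO-2 library. In 46.3% of genes the 4 knockout libraries all lay on one side of both control libraries. Chance gives 13.3% only if all libraries are exchangeable whatever their group. Any difference between the groups, whatever its cause, can raise this share, so the comparison with 13.3% does not tell an effect of TREX1 from another difference.

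Among p53 targets, CDKN1A, the cyclin-dependent kinase inhibitor p21, rose from a log2 CPM of 6.79 ± 0.05 in control to 8.25 ± 0.02 in KO-1 and 7.74 ± 0.13 in KO-2 (SD, n = 2 each). That was a log2 fold change of 1.21 ± 0.06 (SE, adjusted p = 1.2e-06). It lies on chromosome 6 from 36676460 to 36687339. MDM2, a ubiquitin ligase (chromosome 12, 68808176 to 68850686), rose by 1.07 ± 0.05 (adjusted p = 1.2e-06) on 3297 to 7037 reads per library. GDF15, a secreted stress cytokine, rose by 1.39 and SESN1, a stress-induced inhibitor of mTORC1 signalling, by 1.07. The apoptosis genes FAS (1.15), BBC3 (1.04) and BAX (0.44) also rose, as did PPM1D (0.69), the phosphatase that ends p53 signalling. The member that fell was DDB2, a damage recognition factor of nucleotide excision repair, at -0.30, and XPC, of the same pathway, stood at -0.06 (adjusted p = 0.58). The call of DDB2 was lost without control replicate 1 (adjusted p = 0.29), control replicate 2 (0.16), or either KO-1 library (0.081 and 0.093). The count was again 31 rising and 1 falling when adjusted over the list alone. The list stood apart from other genes by camera (adjusted p = 9.2e-20), with an adjusted p = 0.14 with an estimated correlation.

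Chemokines led the NF-kB targets. CXCL8 and CXCL1 attract neutrophils. CXCL8 rose by 1.79 ± 0.11 (SE, adjusted p = 3.4e-06), and CXCL1 was 3.48-fold higher (adjusted p = 1.5e-05). CXCL8 lies on chromosome 4 from 73740506 to 73743716 and rested on 184 to 723 reads per library. CCL20, which attracts lymphocytes and dendritic cells, rose by 1.48, the macrophage growth factor CSF1 by 0.70 and IL6 by 1.06. NFKBIA, the inhibitor that NF-kB induces against itself, rose by 0.68. Of the subunits, NFKB2 rose by 0.44, while NFKB1 (0.13, adjusted p = 0.10) and RELB (0.15, adjusted p = 0.35) did not pass the test. The camera test gave an adjusted p = 9.2e-13 for the list and an adjusted p = 0.10 with an estimated correlation, and 20 members rose when adjusted over the list alone. Immediate early genes, the fast transcriptional response to growth and stress signals, rose in 13 of 19 cases with 1 falling (median 0.43, camera adjusted p = 9.0e-06, adjusted p = 0.10 with an estimated correlation). FOSL1 rose by 1.38, FOS by 0.73 and JUNB by 0.72, while SRF fell by 0.23, a call lost without control replicates 1 and 2 (adjusted p = 0.21 and 0.24) and without KO-1 replicates 1 and 2 (0.12 and 0.13).

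The fallen replication genes spanned origin licensing, nucleotide supply and chromatin assembly. RRM2, the regulated subunit of ribonucleotide reductase (chromosome 2, 10120698 to 10131419), fell by 0.86 ± 0.06 on the log2 scale (adjusted p = 7.7e-06). E2F1, the transcription factor of S phase entry, had a log2 fold change of -0.91, the histone chaperone ASF1B -0.84 and the helicase cofactor CDC45 -0.79. The MCM2 to MCM7 core of the helicase was lower by less, from -0.57 for MCM6 to -0.15 for MCM2, whose call was lost without control replicates 1 and 2 (adjusted p = 0.27 and 0.19) and KO-1 replicates 1 and 2 (0.11 and 0.10). PCNA (-0.17, adjusted p = 0.051) and CCNE1 (0.07, adjusted p = 0.51) did not pass the test. The list gave a camera adjusted p = 9.9e-14 and an adjusted p = 0.19 with an estimated correlation, and 37 members fell when adjusted over the list alone. G2/M genes fell in 15 of 42 cases with 1 rising (median -0.18, camera adjusted p = 8.0e-05, adjusted p = 0.50 with an estimated correlation), among them AURKA at -0.47 and CDC20 at -0.36. ECT2 was the member that rose, by 0.19, a call lost without control replicates 1 and 2 (adjusted p = 0.14 and 0.15) and KO-1 replicate 2 (0.086).

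DNA repair genes fell in part. Of 27 genes of homologous recombination and the Fanconi anaemia pathway, 12 fell and 1 rose (median -0.28, camera adjusted p = 1.3e-05, adjusted p = 0.10 with an estimated correlation). XRCC3 fell to -0.70, BRCA1 to -0.51 and FANCI to -0.40, while RAD51C rose by 0.39. In the ATR and single-stranded DNA list 10 of 27 fell and 2 rose (median -0.12, camera adjusted p = 0.012, adjusted p = 0.43 with an estimated correlation). RPA1, the large subunit of the single-stranded DNA binding complex, stood at -0.69, CLSPN at -0.46 and the nuclease DNA2 at -0.48, while WEE1 and HUS1 rose by 0.33 and 0.35. For nucleotide excision repair 6 of 23 fell, among them ERCC2 at -0.38, and GTF2H1 rose by 0.31, with a median of -0.00 and no call for the list (camera adjusted p = 0.38). Without control replicates 1 and 2 the calls of RAD51C (adjusted p = 0.084 and 0.051), HUS1 (0.22 and 0.079) and GTF2H1 (0.086 and 0.071) were lost, and HUS1 lost its call without KO-1 replicate 1 as well (0.082). With adjustment over the list alone 16 genes of homologous recombination fell, and the counts of the other lists in this paragraph stayed as given.

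**Figure D2:**
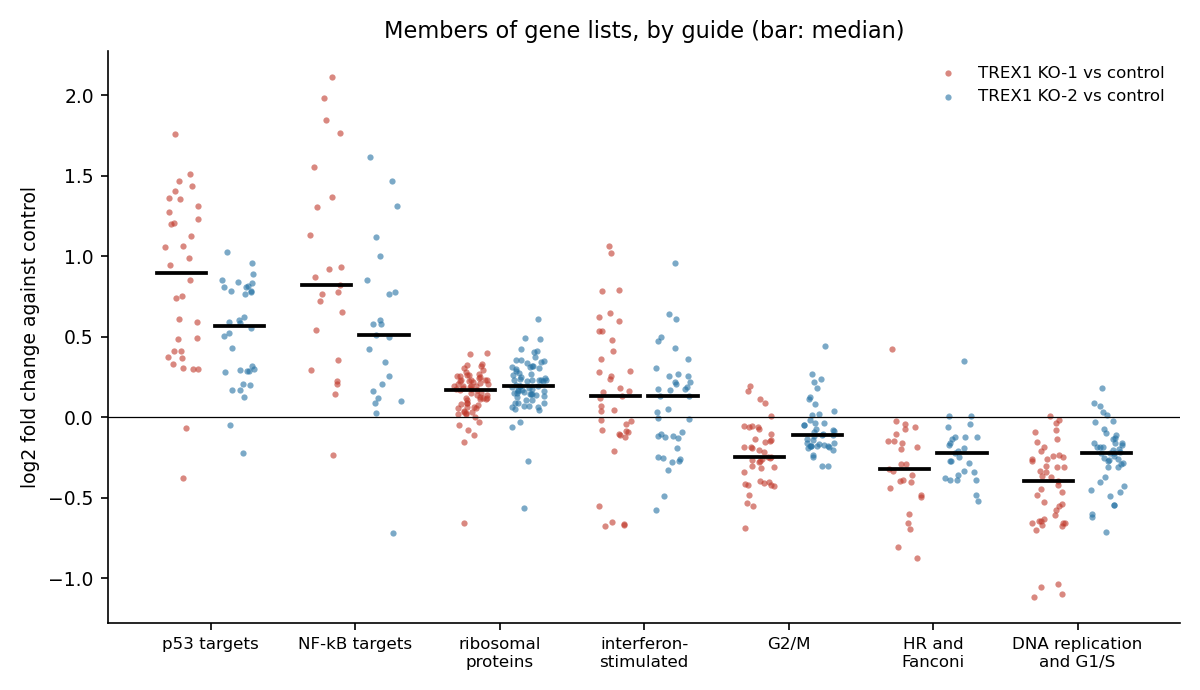
Log2 fold change against control (vertical) of each tested member of 7 gene lists, with KO-1 in red, KO-2 in blue and a bar at each median. The p53 and NF-kB targets lie mostly above 0, at medians of 0.90 and 0.82 for KO-1 and 0.57 and 0.51 for KO-2, and the replication genes lie mostly below 0, at -0.40 and -0.22.

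Interferon-stimulated genes gave a camera adjusted p = 0.077, and an adjusted p = 0.21 with an estimated correlation. By fry, which asks only whether the genes move one way on balance, the adjusted p was 0.041, and without control replicate 1 camera gave 0.041. IFIT2, an antiviral translation inhibitor, rose by 1.01 and SP100, a nuclear body protein, by 0.70. DTX3L (0.36) and PARP14 (0.31), which act together in ADP-ribosylation, rose too, and the call of each was lost without control replicate 1 (adjusted p = 0.074 and 0.098). The antiviral synthase OAS3 stood at -0.57 and the interferon regulator IRF7 at -0.48, and both fell. The calls of IFIT2 and IRF7 were lost without control replicate 1 (adjusted p = 0.13 and 0.26), and that of IRF7 without control replicate 2 (0.23) and KO-1 replicates 1 and 2 (0.095 and 0.079). ISG15 (-0.16, adjusted p = 0.51), MX1 (-0.14, adjusted p = 0.76) and IFIT1 (0.02, adjusted p = 0.94) did not pass the test. The 95% interval of the log2 fold change lay below 1 for 32 of 39 members (82.1%) and below 0.72, the median of the p53 list, for 29 of 39 (74.4%). The counts over the list alone were the same, 9 and 2.

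Of the interferon ligands and T cell chemokines 1 gene was tested, CXCL16, which rose by 0.51 (adjusted p = 0.0082, lost without control replicate 1 at 0.14). Of the 17 tested genes of nucleic acid sensing, 3 rose and 5 fell (median -0.09, camera adjusted p = 0.54). STING1, the adaptor of the pathway, rose by 0.21, and IRF3, the transcription factor it activates, stood at -0.32 and fell. The list of nucleic acid metabolism genes mutated in interferonopathies and of other DNases had 14 genes tested, of which 1 rose and 2 fell (median -0.13, camera adjusted p = 0.12). DNASE1 rose by 0.42, and SAMHD1 (-0.37) and MUS81 (-0.34) fell. Leaving out control replicate 1 ended the calls of IRF3 (adjusted p = 0.14), DNASE1 (0.20), SAMHD1 (0.078) and MUS81 (0.094), and leaving out control replicate 2 those of IRF3 (0.066), SAMHD1 (0.080) and MUS81 (0.067). STING1 lost its call without control replicates 1 and 2 (adjusted p = 0.25 and 0.16) and KO-1 replicates 1 and 2 (0.071 and 0.13).

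For MHC class I, 7 of 23 rose and 0 fell (median 0.12, camera adjusted p = 0.0095, adjusted p = 0.25 with an estimated correlation). TAP1, a subunit of the peptide transporter, rose by 0.68, HLA-C by 0.45, and the NKG2D ligand MICB by 0.59. MHC class II had 3 genes tested and none called. Of 13 immune checkpoint ligands 9 rose and 1, CD47, fell, a call lost without control replicate 1 at adjusted p = 0.16 (median 0.40, camera adjusted p = 9.6e-05, adjusted p = 0.17 with an estimated correlation). VTCN1 rose by 1.03 and VSIR by 0.98, both inhibitory ligands of T cells, NT5E, which makes adenosine, by 0.54, and CD276 by 0.40. CD274 was not analysed here. Adjusted over the list alone, 8 MHC class I genes rose, and the checkpoint counts stayed at 9 and 1.

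Ribosomal protein genes moved by little: 38 of 67 rose and 1 fell, with a median of 0.19 (camera adjusted p = 2.3e-11, adjusted p = 0.21 with an estimated correlation). Of the 67, 10 rose without either control library, 22 and 23 without KO-1 replicates 1 and 2, 4 with no mean-variance trend and 23, with 3 falling, under quantile normalization. RPLP2 rose by 0.35 and RPS19 by 0.33, and RPL27 fell by 0.47 on the log2 scale. Histone genes, whose transcripts mostly lack a poly(A) tail, rose in 7 of 15 cases with 0 falling (median 0.47, camera adjusted p = 0.0089, adjusted p = 0.19 with an estimated correlation), led by H2BC12 at 0.84. Epithelial markers rose in 12 of 23 cases with 1 falling (median 0.30, camera adjusted p = 0.00029, adjusted p = 0.14 with an estimated correlation), with the keratin KRT19 at 0.47 and the tight junction gene CLDN1 at 0.50. Mesenchymal and matrix genes also rose, 11 of 31 with 2 falling (median 0.15, camera adjusted p = 0.0095, adjusted p = 0.17 with an estimated correlation), with COL1A2 at 0.49 and the YAP targets CCN1 and CCN2 at 0.45 and 0.47. With KO-2 alone 7 of these genes rose and 4 fell, and the list was not called (camera adjusted p = 0.14).

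Hypoxia and glycolysis genes (9 of 31 higher, 3 lower, median 0.15, camera adjusted p = 0.026, adjusted p = 0.19 with an estimated correlation) were led by the glucose transporter SLC2A1 at 0.60, and PFKL fell to -0.37. For ATF4 and the unfolded protein response 11 of 32 rose and 5 fell (median 0.12, camera adjusted p = 0.043, adjusted p = 0.19 with an estimated correlation), with SLC7A11, the cystine transporter, at 0.49 and PSAT1, of serine synthesis, at -0.23 (call lost without control replicate 1, adjusted p = 0.083). The call for this list was lost without control replicate 1 (adjusted p = 0.058), control replicate 2 (0.051) or KO-2 replicate 1 (0.068), and that for hypoxia without control replicate 2 (0.051). Under quantile normalization both lists lost their call (0.18 each), and ATF4 also did with a mean log2 CPM of at least 2 (0.063), the knockout libraries as 1 group (0.067) and thinned reads (0.064). Cholesterol synthesis genes went both ways, with 4 of 25 higher and 5 lower (median -0.03, camera adjusted p = 0.71), and LSS stood at -0.65. Of 6 tested markers of leukocytes, endothelium and red cells 0 rose and 1, CDH5, fell (median 0.08, camera adjusted p = 0.85). CDH5 lost its call without control replicates 1 and 2 (adjusted p = 0.33 and 0.094) and KO-1 replicate 2 (0.096). Mitochondrially encoded genes were not analysed here. With adjustment over the list alone, ribosomal counts were 44 and 1, epithelial 13 and 2, and hypoxia 11 and 5.

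Of the 22 lists tested, camera with the preset correlation called 15, and with an estimated correlation it called 0, with 6 at an unadjusted p below 0.05 and a lowest adjusted p of 0.10. Fry called 18. Counts of called members also fell with a control library left out. Without control replicates 1 and 2, replication genes falling numbered 18 and 14, G2/M genes 6 and 5, and homologous recombination genes 4 and 7. Those of ATR signalling numbered 4 and 4, nucleotide excision repair 2 and 2, nucleic acid sensing 0 and 1, and TREX1 neighbours 0 and 1. Interferon-stimulated genes rising numbered 1 and 4, MHC class I genes 3 and 4, immediate early genes 8 and 8, checkpoint ligands 5 and 5, epithelial markers 6 and 5, and p53 targets 22 and 23. For ATF4 4 and 3 rose, for histones 4 and 4, for hypoxia 5 and 5, for mesenchymal markers 7 and 7, and for cholesterol synthesis 2 and 1. Without KO-1 replicates 1 and 2, 7 and 6 epithelial markers, 5 and 4 MHC class I genes, 6 and 6 ATF4 genes and 2 and 1 cholesterol genes rose, and 11 and 9 G2/M genes and 6 and 6 ATR genes fell. The median, mean and camera direction differed in sign for 5 uncalled results: nucleic acid sensing (median 0.01), cholesterol synthesis (-0.01) and the neighbours of TREX1 (-0.01) with KO-1, markers of leukocytes, endothelium and red cells with KO-2 (0.06), and ATF4 and the unfolded protein response between the guides (0.01).

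CMYA5, a muscle scaffold gene, was 5.38-fold higher (log2 2.43 ± 0.41 SE, adjusted p = 0.0017) on 6 to 98 reads per library, and its log2 fold change was 1.55 without control replicate 1 (adjusted p = 0.018) and 3.30 without control replicate 2. BIK, which encodes a proapoptotic BH3-only protein, was 4.89-fold higher (2.29 ± 0.17, adjusted p = 1.5e-05). After these came the long noncoding RNA UCA1 at 1.92, the water channel AQP4 at 1.82, the inositol phosphatase INPP5D at 1.67, the antisense transcript SHROOM3-AS1 at 1.64 and the YAP target ANKRD1 at 1.55. FGFBP1, a carrier of fibroblast growth factors, and the tetraspanin TSPAN11 rose by 1.53 each. CXCL1 and CXCL8 were also among the 12 highest. The call of FGFBP1 was lost without control replicate 1 (adjusted p = 0.051).

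SNRPD2, a core Sm protein of the spliceosome, fell most, to -1.67 ± 0.08 (SE, adjusted p = 1.2e-06), from a log2 CPM of 7.21 ± 0.02 in control to 5.31 ± 0.01 in KO-1 and 5.78 ± 0.21 in KO-2 (SD, n = 2 each). It lies on chromosome 19 from 45687454 to 45692569 on the minus strand, and its exons overlap those of QPCTL on the other strand. VAT1, a vesicle amine transport homologue (chromosome 17, 43014605 to 43025123), fell to -1.28 ± 0.07 (adjusted p = 1.5e-06), and LIMK1, the kinase of cofilin (chromosome 7, 74082933 to 74122525), to -1.27 ± 0.08 (adjusted p = 3.5e-06). The netrin receptor UNC5B fell to -1.22, and these 4 genes all hold the word GACCGCT in their 3' UTR. RPA1, named above among the ATR genes, holds it too. The others were VSIG10L (-1.32), PHF7 (-1.32), the ubiquitin ligase adaptor SPSB4 (-1.27), QRICH2 (-1.26), the inositol trisphosphate kinase ITPKA (-1.23), the fructose kinase KHK (-1.19), the Polycomb protein CBX7 (-1.19) and the Hedgehog effector GLI1 (-1.14). Leaving out control replicate 1 ended the calls of VSIG10L (adjusted p = 0.086), KHK (0.095), CBX7 (0.079) and GLI1 (0.16), and leaving out control replicate 2 those of QRICH2 (0.059), ITPKA (0.056) and KHK (0.086). Exons of UCA1, TSPAN11, VSIG10L, KHK, CBX7 and GLI1 overlap an annotated gene on the opposite strand.

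**Figure D3:**
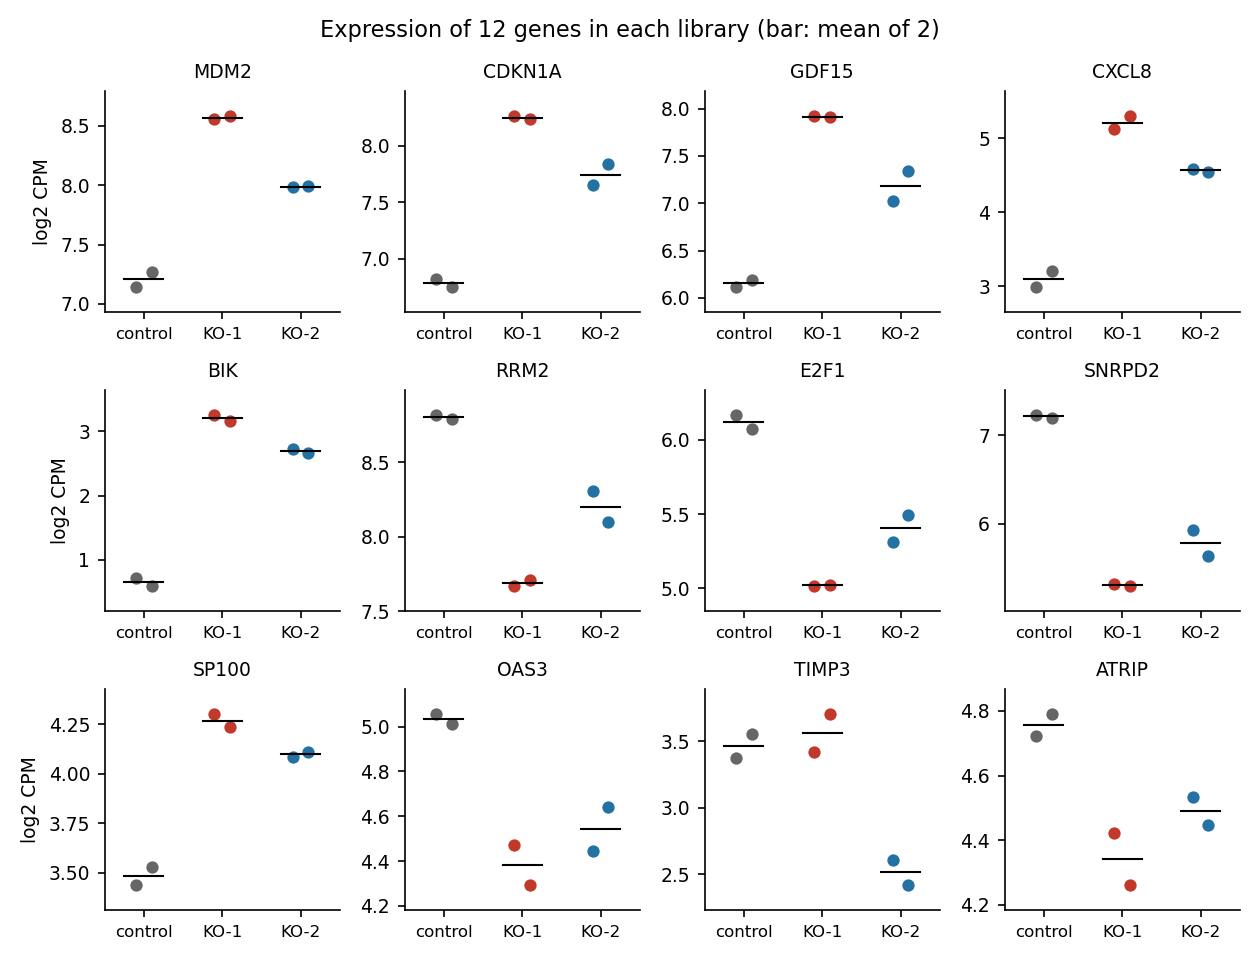
Log2 CPM (vertical) of 12 genes in each library of control (grey), KO-1 (red) and KO-2 (blue), with a bar at the mean of the 2 libraries of a group and an axis per gene that does not start at 0. MDM2, CDKN1A, GDF15, CXCL8 and BIK lie above both control libraries in all 4 knockout libraries, RRM2, E2F1 and SNRPD2 lie below them, and TIMP3 is lower in KO-2 alone, at 2.51 against 3.47 in control and 3.56 in KO-1.

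Taken alone, each guide moved the p53, NF-kB and replication lists the same way. By camera, mesenchymal markers and hypoxia were called with KO-1 (adjusted p = 0.00057 and 0.014) but not KO-2 (0.14 and 0.11). The ATF4 list was called with neither (0.084 and 0.0503). Ribosomal proteins, 35 of 67 rising, had the second-lowest adjusted p with KO-2 (3.0e-15). With an estimated correlation no list was called with either guide (lowest adjusted p 0.098 and 0.14). With KO-1, 30 of 34 p53 targets rose and 1 fell, 19 of 23 NF-kB targets rose, and 35 of 45 replication genes fell. With KO-2, 22 p53 targets and 14 NF-kB targets rose and 16 replication genes fell. KO-1 against control called 4089 genes, 2005 higher and 2084 lower, and KO-2 against control called 2329, 1201 higher and 1128 lower. With library medians set equal the splits were 2535 to 1653 for KO-1 and 1575 to 866 for KO-2. The count for KO-1 ranged from 1683 without control replicate 1 to 6254 without KO-2 replicate 1. That for KO-2 ranged from 359 without control replicate 1 to 4564 without KO-2 replicate 2, and with no mean-variance trend it was 162.

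Taken separately, the guides shared 1880 called genes in the same direction, 1004 higher and 876 lower, and 2 in opposite directions. Independent lists of these sizes would share 175 higher and 171 lower genes. Groups simulated with no gene changed, against 1 simulated control group, shared 0. Few calls can be made in such data, so that 0 does not show how many shared calls come from the common controls. Part of the overlap may come from the shared controls, whose 2 libraries were not split between the guides. Across genes the fold changes of the guides correlated at a Pearson r of 0.75, where unchanged groups gave 0.49, and genes are not independent replicates. Their covariance was 0.108 against a simulated 0.0201, a difference of 0.0882. The overlap ranged from 330 without control replicate 1 to 3074 without KO-2 replicate 1.

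**Figure D4:**
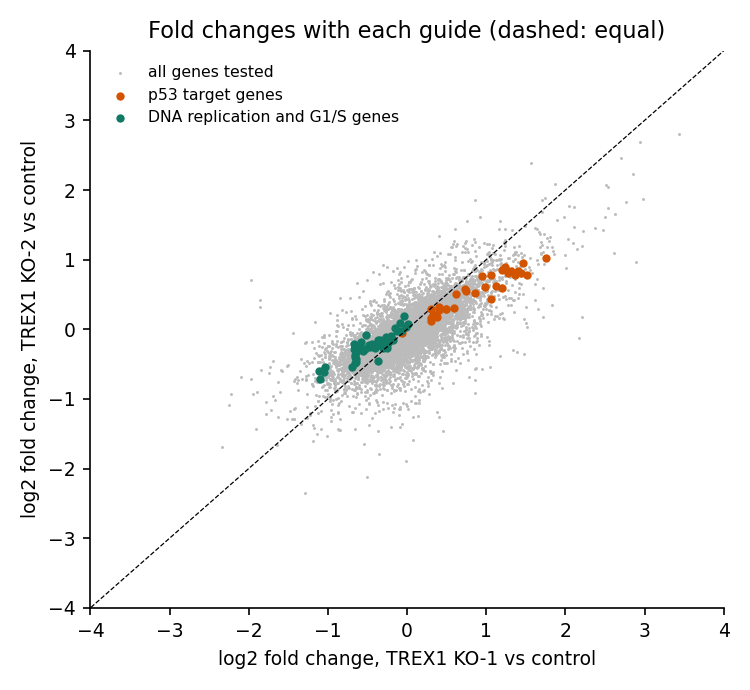
Log2 fold change against control of each gene tested with KO-1 (horizontal) and KO-2 (vertical), with p53 target genes in orange, DNA replication and G1/S genes in green and equal changes on the dashed line. The p53 targets lie mostly below the dashed line on the positive side, and the replication genes above it on the negative side.

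The comparison of KO-2 with KO-1 asked whether the guides differed. In KO-2 the p53 targets were higher than in control by less: 9 of 34 were lower in KO-2 than in KO-1 and 0 were higher, at a median difference of -0.28 (camera adjusted p = 4.1e-16, adjusted p = 0.20 with an estimated correlation). NF-kB targets differed by -0.34, with 3 of 23 lower (camera adjusted p = 6.3e-10, adjusted p = 0.18 with an estimated correlation), and replication genes by 0.18, with 6 of 45 higher (camera adjusted p = 2.4e-14, adjusted p = 0.28 with an estimated correlation). G2/M genes differed by 0.16 with 2 of 42 higher (camera adjusted p = 1.7e-09, adjusted p = 0.50 with an estimated correlation). Of the 4068 genes called for the mean of both guides, 75.1% changed less in KO-2. Adjusted over the list alone, 20 p53 and 10 NF-kB targets were lower and 15 replication and 6 G2/M genes higher.

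In all, 157 genes differed between the guides, 46 higher and 111 lower in KO-2. Without either KO-1 library limma called 0, with 1274 and 1331 genes at an unadjusted p below 0.05, so every call between guides named here was lost without either of them. It called 43 and 45 without control replicates 1 and 2, 729 without KO-2 replicate 1, 3155 without KO-2 replicate 2, 484 with GC and length trends removed and 1 with no mean-variance trend. The share higher in KO-2 was 29.3% of the 157, and 6.98% and 6.67% without control replicates 1 and 2, 39.8% and 48.7% without KO-2 replicates 1 and 2, 41.3% with GC and length trends removed and 18.1% with a replicate block. Of the 157, 85 had a KO-2 value between those of control and KO-1. MDM2 differed by -0.58 (adjusted p = 0.0036), CDKN1A by -0.51, GDF15 by -0.74, CCL20 by -0.73 and RRM2 by 0.51.

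Higher in KO-2 than in KO-1 were ERBB3, a receptor tyrosine kinase (0.76, adjusted p = 0.026), CHCHD3, of mitochondrial cristae (0.57), ASMTL (0.50) and PHF20 (0.49). ERBB3 stood at -0.76 with KO-1 and 0.00 with KO-2 against control. It was the epithelial marker counted as falling for the mean of both guides (-0.38). Lower were the oxytocin receptor OXTR (-1.33, adjusted p = 0.039), TCIM (-1.05), the metalloproteinase inhibitor TIMP3 (-1.05), the growth factor HBEGF (-0.98) and cardiac actin ACTC1 (-0.94). OXTR and TCIM rose with KO-1 by 1.48 and 1.22 and had values of 0.15 and 0.16 with KO-2. TIMP3 (chromosome 22, 32801701 to 32863043) went the other way, at 0.10 (adjusted p = 0.70) with KO-1 and -0.95 (adjusted p = 0.0046) with KO-2, on 78 to 304 reads per library. TIMP3 and HBEGF hold the word TGCTGTC in their 3' UTR. In 37 of the 157 genes (23.6%) KO-2 lay further from control than KO-1 and was itself called, and all 37 were lower in KO-2.

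The authors' deposited table called 4286 genes for KO-1 against control, 2465 for KO-2 against control and 220 for KO-2 against KO-1. Of these, 4078, 2312 and 156 were also called here in the same direction, and the fold changes correlated across genes at a Pearson r of 0.997, 0.987 and 0.982. The authors' deposited table gives MDM2 a log2 fold change of 1.36 for KO-1 and 0.78 for KO-2 against control, and ATRIP -0.42 and -0.27.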

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

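The guides were compared directly, and 157 genes differed by that test. The removal of depth, GC and length trends was added after the fold changes were seen, as was the scan of words in 3' UTRs. Among named genes, the log2 difference of KO-2 from KO-1 was -0.65 for CXCL8, -0.73 for INPP5D, -0.73 for CCL20, -0.58 for MDM2, -0.51 for CDKN1A, -0.74 for GDF15, -0.47 for SESN1, -0.40 for CCN2, -0.46 for CCN1 and -0.36 for SLC7A5. It was 0.47 for SNRPD2, 0.51 for RRM2, 0.44 for ASF1B, 0.49 for CDC45, 0.44 for AURKA, 0.35 for CDC20, 0.76 for ERBB3, 0.57 for CHCHD3, 0.50 for ASMTL and 0.49 for PHF20. OXTR (-1.33), TCIM (-1.05), TIMP3 (-1.05), HBEGF (-0.98) and ACTC1 (-0.94) were lower in KO-2. All of these calls were lost without either KO-1 library, where 0 genes were called by limma and 1274 or 1331 had an unadjusted p below 0.05.

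By camera at the preset correlation, 12 lists differed between the guides, and none did with an estimated correlation. Their median differences were -0.34 for NF-kB targets, -0.28 for p53 targets, -0.28 for histone genes, -0.20 for immediate early genes, -0.11 for mesenchymal markers, -0.10 for checkpoint ligands and -0.0839 for hypoxia. They were 0.18 for DNA replication, 0.16 for G2/M, 0.11 for homologous recombination, 0.0693 for ATR signalling and 0.0514 for ribosomal proteins. With GC and length trends removed ribosomal proteins lost their call (median 0.01, camera adjusted p = 0.42). Under quantile normalization ATR signalling and histone genes lost theirs (camera adjusted p = 0.055 each). Histone genes also did with thinned reads (0.052), and hypoxia with a mean log2 CPM of at least 2 (0.053). Without KO-2 replicate 1 the calls of ATR signalling (adjusted p = 0.55), ribosomal proteins (0.90) and hypoxia (0.080) were lost. Without KO-2 replicate 2 those of homologous recombination (0.059) and histone genes (0.059) were, without KO-1 replicate 1 those of ATR signalling (0.13) and hypoxia (0.050), and without KO-1 replicate 2 those of ribosomal proteins (0.071), hypoxia (0.052) and histone genes (0.24).

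The rise of p53 targets and the fall of replication genes with both guides was weighed first. With all libraries thinned to 1 total, the p53 median was 0.68 and the replication median -0.31, so the number of reads alone does not account for them. Thinning draws all genes of a library at the same rate, so genes with many reads could hardly move. It cannot test other differences between libraries that go with depth. With GC and length trends removed the medians were 0.75 and -0.29, which argues against that bias. The design holds 1 control population, so a property of that population, or of carrying a cutting Cas9, cannot be told from the loss of TREX1. DNA breaks made by Cas9 may raise p53 targets by themselves, and the 1 control population leaves this open.

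The smaller change of the p53 and NF-kB lists in KO-2 was weighed second. Without KO-2 replicate 1 the median p53 difference was -0.18 in place of -0.28, between the values set beforehand for and against that library as the cause. If KO-2 libraries were a mixture of KO-1-like and control-like cells, few genes should lie further from control in KO-2 than in KO-1. Of all 157 genes 23.6% did, above the 10% set beforehand as evidence against a mixture, so a mixture alone does not account for these 37 genes. The 95% interval of 17% to 31% treats genes as independent, which they are not. Of the 37, 27 (73.0%) hold the word TGCTGTC in their 3' UTR, against 16.8% of 12225 genes. That word was found in the same fold changes. The share thus rests largely on genes with 1 word, and a mixture together with a separate effect on such genes was not tested. None of these 37 genes is in the p53 or NF-kB list. All 9 p53 targets and all 3 NF-kB targets called between the guides had a KO-2 value between control and KO-1. A mixture would put them there too, and whether it adds to the smaller change of those lists was not tested.

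Words in 3' UTRs were weighed last, in a scan chosen after the genes further from control in KO-2 were seen to be all lower. Genes holding GACCGCT were lower with both guides (205 genes, score -7.81, lowest permuted -5.55), and those holding TGCTGTC were lower in KO-2 than in KO-1 (2051 genes, score -7.51, lowest permuted -5.43). The base composition of 3' UTRs, beyond the GC trend that the scan removed, was not tested as a cause, and genes with the word in their coding sequence alone were lower too, by less (-0.06 and -0.02). If a small RNA paired with these sites, a following A should deepen the shift. For GACCGCT it did so by -0.16 (SE 0.107), a prediction written beforehand and met at under 2 standard errors. That difference rests on 22 genes with a following A, among them SNRPD2 (-1.67), the named gene that fell most. For TGCTGTC the shift deepened by -0.0242 (SE 0.0114), a prediction written afterwards. No small RNA was measured, so its source, including the guide construct, is a hypothesis that these 2 differences do not settle.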

How the results depend on the processing

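The first settings were fixed before the data were seen; voom, thinning and the GC and length correction were chosen afterwards. No called result changed direction. The split for both guides turned from 2011 higher and 2057 lower to 2575 and 1598 with equal medians. Uncalled list medians changed sign for cholesterol (-0.03 to 0.02 with equal medians, 0.03 with GC and length trends removed and 0.00 without KO-1 replicate 1), TREX1 neighbours (-0.04 to 0.03 with a mean log2 CPM of at least 2 and 0.00 with equal medians), nucleotide excision repair (-0.00 to at most 0.05, with equal medians) and MHC class II (0.22 to -0.05 without control replicate 2). With no mean-variance trend, counts for both guides, KO-1, KO-2, KO-2 against KO-1 and genes called in both guides in the same direction were 2201, 2345, 162, 1 and 152. At an absolute log2 fold change of at least 1 they were 188, 308, 106, 3 and 77, and at an adjusted p under 0.01 they were 2126, 2225, 759, 31 and 652, by construction. With GC and length trends removed 484 genes differed between guides. With a mean log2 CPM of at least 2, 12 of the 24 named genes remained, since fewer genes were tested. Camera with an estimated correlation called 0 lists, and fry gave the interferon list an adjusted p of 0.041. Leaving out 1 library gave 1277 to 6064, 1683 to 6254, 359 to 4564, 0 to 3155 and 330 to 3074 genes, and 0.041 to 0.18 for the interferon list. The lone library left in a group is assumed to vary like the other groups. Leaving out a library of a group outside a comparison leaves its fold changes as they were. OXTR, for example, differed between the guides by -1.33 with either control library left out. Calls gained or lost in that way come from the shared variance estimate, its degrees of freedom and the genes tested, not from the fold changes. Apart from this and the construction named, the cause was not tested.

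Of the other values, 189 for lists, 138 for lists between guides, 1413 for named genes and 259 for named genes between guides kept direction and call, and 5, 5, 35 and 37 lost the call. With a library left out 86, 62, 613 and 68 kept it, and 4, 10, 65 and 82 lost it. A replicate block gave 3782, 3829, 2054 and 105 genes and 1681 genes called in both guides in the same direction, with correlations of replicate deviations of -0.05, 0.04 and -0.04, so the numbers mark no shared batch here. The knockout libraries as 1 group gave 2925 genes. The histone list was not run with GC and length trends removed, and settings that need a TREX1 value were not run. Depth limits genes with few reads: at 13222933 reads, 1 read was 0.0767 CPM.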

Other observations

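These genes were chosen after their values were seen. Genes described as p53 targets but outside the list were higher: DRAM1, a regulator of autophagy (1.41), PIDD1, a death domain protein (1.10), and RPS27L, a ribosomal protein homologue (1.02). SNRPD2 (-1.67) moved apart from the other Sm genes: SNRPD1 (0.20), SNRPE (0.26), SNRPF (0.32) and SNRPG (0.24) rose, and SNRPD3 (0.13, adjusted p = 0.22) and SNRPB (0.12, adjusted p = 0.24) did not pass the test. QPCTL, which overlaps SNRPD2 on the opposite strand, fell to -0.56.

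The cytidine deaminase APOBEC3C rose by 1.47 while its paralogue APOBEC3B fell to -0.39. The inflammasome cytokine IL18 rose by 0.85. On chromosome 17q21 VAT1 (-1.28), RND2 (-0.82), BRCA1 (-0.51) and RPL27 (-0.47) fell. Around 55 genes that fell at least 2-fold, 56 neighbours within 20 kb had a median of -0.14, where the inner 95% of 1000 random draws lay from -0.11 to 0.06 and 0.9% of draws were as low, and 17 of them fell and 3 rose. Medians of the 23 chromosomes with at least 100 genes lay between -0.09 and 0.06.

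The highest-scoring word in 3' UTRs was AGCCTTA with both guides (1399 genes, score 5.25, highest permuted 4.79) and with KO-1 (5.03 against 4.88), but with KO-2 alone it did not pass the permuted scores (4.86 against 4.97). For KO-2 against KO-1 the highest was CAGCTAC (2200 genes, score 5.63, highest permuted 4.99). GACCGCT ranked first from the bottom in each of the 4 knockout libraries against the control mean. The word was picked from the mean of these same libraries, so these ranks are not separate evidence for it. Between the control libraries GACCGCT scored -0.36, or 0.36 with the same difference taken the other way. Its mean shift was -0.19 (SE 0.03) in 3' UTRs and -0.06 (SE 0.01) where the word lay in the coding sequence alone. For TGCTGTC, between the guides, it was smaller, at -0.05 (SE 0.0053) in 3' UTRs and -0.02 (SE 0.0059) in the coding sequence alone.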
